A study of Colocasia esculenta with 4 samples.

How the data were processed

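RNA came from the shoot apex of taro (Colocasia esculenta), a corm crop of the arum family. Per the labels' protocols, the apical meristem was cut out together with the youngest leaves around it. Polyadenylated RNA was made into 4 strand-specific libraries and sequenced from one end on an Illumina HiSeq 2000, per the labels' protocols. The labels name the 4 libraries as replicates of 1 tissue of 1 cultivar. They do not say whether these came from separate plants, so the spread between them, and any p-value resting on it, may be technical. No library carries another tissue, treatment or cultivar, and no comparison between conditions was made.

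The deposited count files hold whole read counts per gene, made by the authors with featureCounts 2.0.0, per the file headers. The headers record that reads were assigned to exons and summed per gene on the reverse strand, and that reads aligning to more than 1 place were counted at each place. Per the submitters' processing notes, Trimmomatic 0.36 and HISAT2 2.0.5 were used before counting, together with FastQC and SAMtools. The headers name a Lachesis-scaffolded taro assembly and its gene annotation, without a build name. Coordinates below are those of the count files, counted from 1. The annotation holds 28695 genes on 14 linkage groups (LG01 to LG14, the chromosome-scale sequences) and 1331 unplaced contigs.

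The authors also deposited a workbook with the same counts and with RPKM values. The counts of all 28695 genes in it equalled those of the per-library files. Its 3 footer lines hold the totals used for scaling and were kept out of all sums. The deposited RPKM values were the counts divided by exon length in kilobases and by the library's assigned total on the usual RPKM scale. Recomputing them from the counts gave the same value for 28695 genes within 1e-06. Both numerator and total include reads counted at more than 1 place. The number of sequenced or aligned reads is not given in the sources used here.

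The files pair no gene identifier with a gene name, product or sequence, and no reference was used here. A set of 30 gene lists (profilin, actin, mannose-binding lectin, calcium-binding, protease, allergen, meristem, leaf, storage and other families) had been fixed before the data were examined. Of these, 0 could be filled, so the planned levels of gene lists, comparisons between them and shares of their leading members were not computed. The rule for naming genes, fixed at the same time, allowed at most 2 identifiers per part when no names could be had. The parts were the genes highest in mean RPKM, the lists, and the genes with excess variation. Further identifiers, chosen after their values were seen, are marked as such.

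CPM values (counts scaled to the library's total) were computed from each library's counts. A gene was called detected with at least 1 CPM in every library. A count of 0 allows up to 3 counts, which corresponds to 0.118 to 0.135 CPM in these libraries and covers counting error only. Exon numbers were obtained after merging overlapping exons of a gene. Replicate spread was estimated with edgeR 4.0.16 in R 4.3.3 with an intercept-only model, TMM scaling and genes that had 1 CPM in every library or passed edgeR's default expression filter. Genes with excess variation were sought by dividing each gene's quasi-likelihood dispersion by the prior value for its abundance. The ratio was set against an F distribution and adjusted by the Benjamini-Hochberg method at 0.05. DESeq2 1.42.0 gave an alternative count from its dispersion outliers, which are marked by a different rule without adjusted p-values. Each pair of libraries was also compared by a chi-square statistic over genes with at least 20 counts in the pair.

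The edgeR procedure was tested on simulated data in which 200 genes had a raised dispersion. With 1 dispersion trend for all other genes, it recovered 39.5% of genes whose dispersion was 10 times higher and 42% of those at 30 times, among 10241 and 10142 genes. With dispersions scattered around the trend with the fitted prior degrees of freedom (2.36), it recovered 0 genes at either size, among 9814 and 9793 genes. These sets were noisier than the libraries, with a common biological coefficient of variation of 44.1% and 44.2% against 27.3%. The scattered dispersions were therefore scaled down until a set without planted genes had 27.3%, with fitted prior degrees of freedom of 2.76. With genes planted in such sets it again recovered 0 at either size, among 10150 and 10123 genes.

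Division of the annotation by read content was made after the data were seen. Linkage groups with fewer than 10% of genes detected are called low-read. A run of at least 20 genes with no count at the end of another linkage group is called a terminal block, and the rest is called read-bearing. Gene pairs with equal exon lengths were pairs of genes of at least 2 exons that shared the same ordered exon lengths with each other and with no further gene. Python analyses used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were other detection floors, other scalings, no filter, other tolerances for gene pairs, and leaving out each library in turn.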

Results

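The transcriptome of the taro shoot apex was profiled in 4 replicate libraries of a single cultivar. The series title places these libraries in a study of the proteins associated with raphides, the needle-shaped calcium oxalate crystals of taro, and names profilin and allergens. The count tables held 22301051 counts for replicate 1, 25434148 for replicate 2, 23365618 for replicate 3 and 22252534 for replicate 4. At least 1 read was counted for 12804, 12646, 12895 and 12646 genes in replicates 1 to 4. With a single group, the data allow genes to be set against each other, parts of the genome against each other, and replicates against each other.

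Transcript abundance in the apex covered a wide range. Of 28695 annotated genes, 9811 (34.2%) reached at least 1 CPM in every library, 11729 had at least 1 count in every library, and 14734 (51.3%) had no count in any. Parts of the annotation with few or no counts, described below, held 49.3% of all genes. The 34.2% and 51.3% therefore do not measure how many genes were expressed or silent in the apex. Among the 9811 genes, the median of the mean RPKM was 28.3, the 90th percentile 135 and the 99th percentile 633. The 10 most counted genes held 5.05% ± 0.175 of all counts and the 100 most counted held 17.7% ± 0.211 (SD, n = 4).

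The highest mean level was that of EVM0013189, a gene of 2 exons and 1171 bp of exon sequence on the plus strand of LG03 (3108603 to 3110316). It reached 8065 ± 869 RPKM (SD, n = 4) and took 0.944% ± 0.102 of the counts. EVM0022944 followed at 7894 ± 1426 RPKM. It lies on an unplaced contig (Contig10797, 1601 to 2793, plus strand) and has 7 exons within 456 bp of exon sequence. The difference between the 2 means was smaller than either SD, so their order was not resolved. EVM0022944 had the higher mean without replicate 2 (7923 against 7823 RPKM) and without replicate 4 (8485 against 8477 RPKM). The 15 genes highest in mean RPKM ranged from 1591 to 8065 RPKM with coefficients of variation between 3.35% and 32.7%. Of these, 13 had more than 1 exon and 4 lay on unplaced contigs.

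EVM0006662 came next at 7370 ± 1700 RPKM (SD, n = 4), not resolved from the gene ranked after it (6879 ± 2000 RPKM). EVM0006662 was chosen for mention after its values were seen. It also has 7 exons, within 474 bp, and lies on LG07 (86480490 to 86482588, plus strand). Its counts were 102%, 98.4%, 95.2% and 89.6% of those of EVM0022944 in replicates 1 to 4. Because reads aligning to more than 1 place were counted at each, the levels of genes with a near-identical copy are uncertain, and the data do not tell whether these genes share reads.

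Counted reads were spread unevenly over the assembly. On LG03, LG05, LG09, LG11, LG12 and the unplaced contigs, between 58.6% and 69.4% of annotated genes were detected. On the 8 linkage groups LG01, LG02, LG04, LG06, LG08, LG10, LG13 and LG14, the detected share lay between 1.66% and 6.37%, and these groups were set apart by that share after the data were seen. These 8 groups carry 11702 genes, 40.8% of the annotation, and received 1.13% ± 0.10 of the counts (SD, n = 4). Of their genes, 1654 had any count, with a median of 5 counts summed over the libraries. The 14541 genes of the read-bearing part held 98.9% ± 0.10 of the counts, and 12307 of them (84.6%) had a count, with a median of 2143. LG12 took 14.7% ± 0.11 of the counts and LG02 took 0.0643% ± 0.0029 (SD, n = 4).

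**Figure D1:**
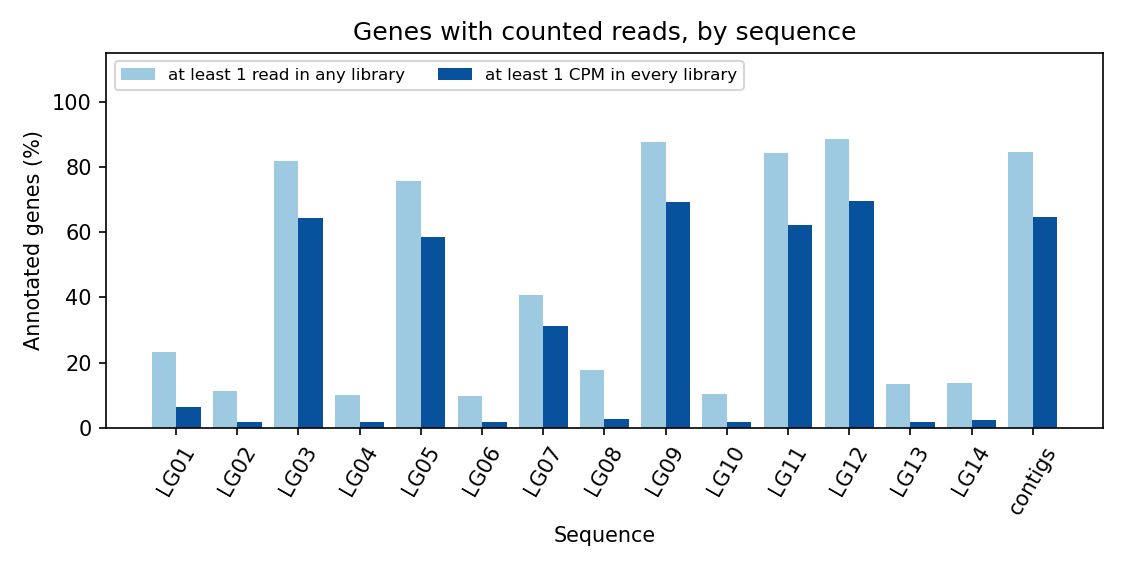
Share of annotated genes (y axis, percent) with at least 1 read in any of the 4 libraries (light bars) and with at least 1 CPM in every library (dark bars), for the 14 linkage groups and the unplaced contigs (x axis). The dark bars stand at 1.66% to 6.37% on 8 linkage groups, 31.3% on LG07 and 58.6% to 69.4% elsewhere.

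LG07 fell into 2 parts. Up to the end of its last counted gene at 112416047, 1837 of 2117 genes (86.8%) had a count and 66.8% were detected. Beyond it, 2399 annotated genes between 112717981 and 169719790 had 0 counts in all 4 libraries. LG03 ended likewise, with 53 genes from 186902457 to 189878844 at 0 counts, after a stretch in which 1579 of 1873 genes (84.3%) had a count. The first 8 Mb of LG05, a boundary not given by the rules that divide the annotation, were intermediate. There 136 of 340 genes (40.0%) had a count, against 1240 of 1476 (84.0%) on the rest. All these genes remain in the read-bearing part. Together the low-read linkage groups and the terminal blocks of LG03 and LG07 held 14154 genes, 49.3% of the annotation. A value of 0 for these genes cannot be read as a gene that was silent in the apex.

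**Figure D2:**
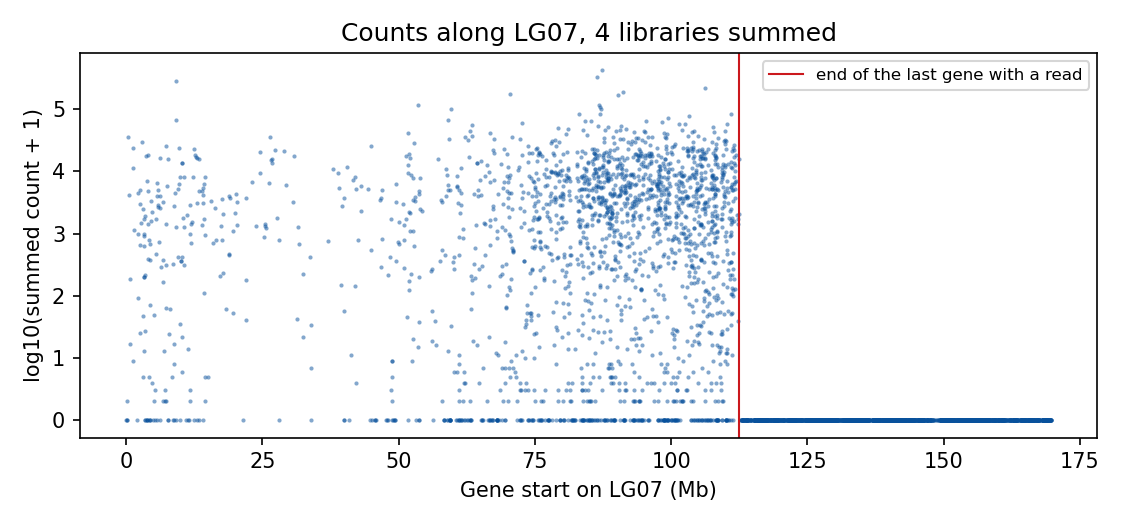
Counts of each annotated gene on LG07 summed over the 4 libraries, as log10(count + 1) on the y axis, against the gene's start in Mb on the x axis. The vertical line marks the end of the last gene with a read (112416047), and the 2399 genes beyond it are all at 0.

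Gene structure was related to detection within the read-bearing part. Of 2956 genes with 1 exon, 39.8% were detected, against 54.3% of 4822 genes with 2 or 3 exons, 82.0% of 5386 genes with 4 to 10 exons and 93.2% of 1377 genes with more than 10. Among detected genes, the median level was 13.8 ± 1.7 RPKM for 1 exon, 23.1 ± 1.1 for 2 or 3, 32.9 ± 0.63 for 4 to 10 and 38.1 ± 2.1 for more than 10 (SD of the libraries' medians, n = 4). Differences between neighbouring classes exceeded the SD of both. Across the 9491 detected genes, Spearman's correlation of RPKM was 0.21 ± 0.03 with exon number and −0.015 ± 0.005 with exon length (mean and SD over libraries). With CPM, which is not scaled for length and on which detection rests, it was 0.347 ± 0.0273 with exon number and 0.396 ± 0.00497 with exon length. The rise of the detected share with exon number was therefore not separated from exon length. These are correlations across genes, which are not independent replicates.

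Possible copies of a gene were sought as pairs with the same ordered exon lengths. No sequences were compared, so whether such pairs are copies is not known. In 74 such pairs the more counted gene lay in the read-bearing part and had at least 100 counts. Where the partner also lay there (49 pairs), its count was a median 90.8% of the other's, and 44 partners reached at least 10%. Where the partner lay on a low-read linkage group or terminal block (25 pairs), 0 reached 10% and 24 had no count. That contrast follows in part from how the parts were defined, since 87.4% of all 11377 genes with at least 2 exons on the low-read parts and terminal blocks had no count. In 19 of the 49 pairs (38.8%) both genes had counts within 10% of each other in all 4 libraries. Genes adjacent in rank of summed count did so in 726 of 8575 cases (8.47%).

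**Figure D3:**
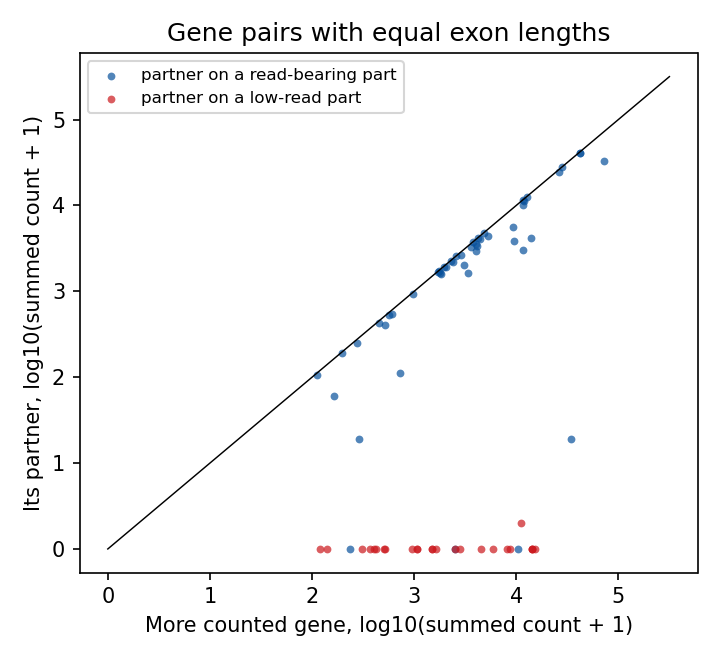
Counts of the partner (y axis) against those of the more counted gene (x axis), both as log10(summed count + 1), for 74 gene pairs with equal exon lengths. Of the 49 pairs with both genes in the read-bearing part (blue), 44 partners had at least 10% of the other's count, while 24 of the 25 partners on low-read parts (red) lie at 0, and the line marks equal counts.

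The replicates were highly correlated, and replicate 4 was the least so. Pearson's correlation of log2 CPM across the 9811 detected genes was 0.984 between replicates 1 and 2, 0.985 between 1 and 3, and 0.978 between 2 and 3. It was 0.951, 0.952 and 0.942 between replicate 4 and replicates 1, 2 and 3. The chi-square statistic per degree of freedom was between 34.6 and 57.9 among the first 3 libraries and between 128 and 143 for pairs with replicate 4, against about 1 for counting noise alone, which leaves out other differences between libraries and reads counted at more than 1 place. No pair of libraries differed by as little as counting noise. The first principal component of log2 CPM held 66.8% of the variance, with replicate 4 at 52.6 and the others between −24.9 and −11.4.

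In replicate 4, 176 genes lay more than 2-fold above all 3 other libraries and 322 more than 2-fold below, 498 of 9811 in all. The corresponding numbers were 6 above and 14 below for replicate 1, 32 and 7 for replicate 2, and 124 and 3 for replicate 3. At a floor of 10 CPM the number in replicate 4 was 218 of 7363 genes. The common biological coefficient of variation was 27.3% with all libraries (edgeR, 10349 genes) and 19.4% without replicate 4.

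**Figure D4:**
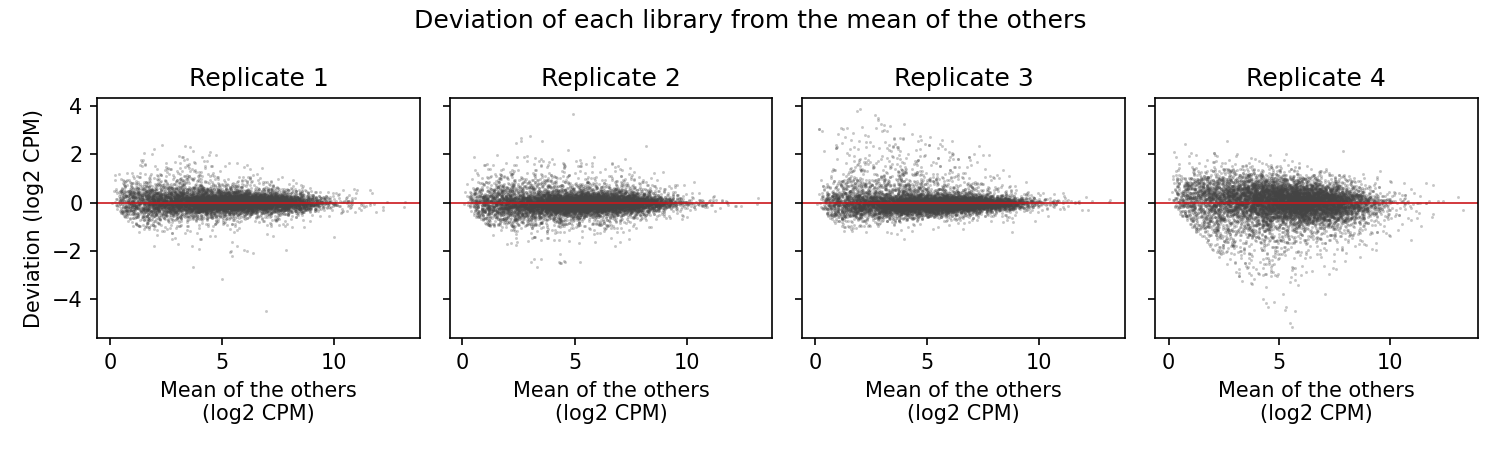
Deviation of each library's log2 CPM from the mean of the other 3 (y axis) against that mean (x axis), 1 point per detected gene, with 1 panel per replicate. The SD of the deviation is 0.34, 0.38, 0.42 and 0.65 in replicates 1 to 4.

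By edgeR's quasi-likelihood dispersions, 0 of 10349 genes varied between replicates by more than genes of like abundance after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.927. At an unadjusted p under 0.05 there were 475 of 10349 genes, a share no larger than the 0.05 expected by chance. DESeq2 marked 33 genes as dispersion outliers, by a different rule without adjusted p-values. Of 200 planted genes with a dispersion 10 times higher, the procedure recovered 39.5% in simulations with 1 dispersion trend for all other genes, and 0 where dispersions were scattered around it at the libraries' common coefficient of variation. The count of 0 therefore does not show that such genes are absent.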

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

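All tests of explanations in this part were chosen after the results were seen. Among 28 values compared over the 4 libraries, 1 had a library far from the other 3. About 1 independent value in 20 is expected to. The 28 values overlap, as shares of single linkage groups and of their sum are both among them. The number expected by chance is therefore not known. The 1 value was the share of counts on the 8 low-read linkage groups, 0.980% in replicate 4 against 1.17%, 1.20% and 1.17% in replicates 1 to 3. The most counted gene of these groups, EVM0006535 on LG13, was singled out after its values were seen. Without it the shares were 0.980%, 0.965%, 1.01% and 0.914% and no library stood apart. Gene by gene, the same rule marked 1204 of 9811 detected genes (12.3%), and replicate 4 was the library apart in 973 of them.

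The low-read parts hold 49.3% of the annotated genes. Genes not expressed in the apex, scattered without regard to position, would not form a block as long as the longest run with no count. That run held 2399 genes, against at most 22 in 200 shuffles. It is the terminal block of LG07, seen before the shuffles, and the low-read linkage groups were not tested separately. Read-bearing genes matched on length and exon number had a count in 85.2% of cases, against 11.7% observed in the low-read parts. That contrast follows in part from how the parts were defined. The median total exon length was 1212 bp on low-read linkage groups and 1438 bp in terminal blocks, against 1209 bp in the read-bearing part. Median exon numbers were 3, 4 and 3. Shorter or simpler gene models therefore do not account for the low-read parts either. A candidate explanation is that gene coordinates on these sequences do not match the sequence to which the reads were aligned, as when annotation and assembly come from different versions. It stays open. Partners of counted genes with equal exon lengths had no count in 96.0% of 25 pairs. Among all genes with at least 2 exons there, 87.4% had no count (exact binomial test, one-sided p = 0.158). Under this explanation partners would be at 0 about as often as other genes there, so the test cannot decide. The aligned sequence was not used here. No biological explanation other than scattered unexpressed genes was tested, and the labels give a single group.

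Replicate 4 deviated most from the other libraries gene by gene. Its gap over the range was 0.812 for the mean correlation, 0.758 for the SD of the deviation and 0.827 for the first principal component. All fell short of Dixon's critical value. The values of the other libraries were computed with replicate 4 included, so the shortfall does not decide whether replicate 4 stands apart. Depth is an unlikely cause, since replicate 1 had nearly the same total (replicate 4 had 99.8% of it) and a deviation SD only 0.521 of that of replicate 4. A trend with gene length, exon number or level explained 5.19% of the variance of the deviation, and the SD after its removal was 0.637, above the 0.417 of the next library. A different mix of cells or tissue in the dissected apex, or a difference between plants, cannot be told apart from other causes, because 0 marker lists could be filled without gene names.

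Pairs with equal counts made up 38.8% of pairs with equal exon lengths in the read-bearing part. Genes adjacent in rank of summed count, not matched in level to these pairs, had equal counts in 8.47% of cases. Whether pairs with equal exon lengths are copies was not examined by sequence. If they are, their higher share could come from reads that align to both genes being counted in each, as the count headers record. Similar regulation of true duplicates would also raise the share, and was not tested.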

How the results depend on the processing

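Of 73 alternatives over 12 results, 57 left the result as it was within the spread or within 1.5 times the count. This tally does not measure stability. Leaving 1 library out of 4 cannot move a mean by more than its SD over the libraries. The edgeR procedure for excess variation recovered 0 planted genes in simulations with scattered dispersions, so its counts of 0 could hardly change. The order of the highest means, EVM0013189 above EVM0022944, turned without replicate 2 (7823 against 7923 RPKM) and without replicate 4 (8477 against 8485 RPKM). The results on parts of the annotation, on gene pairs and on replicate 4, their alternatives, and the restriction of the replicate spread and excess variation to read-bearing genes were chosen after seeing the data. The number of detected genes was between 9835 and 10017 when a library was left out and between 10309 and 11729 at other floors. These floors were all looser, and leaving out a library can only raise a number that asks for every library. The direction of these changes was therefore fixed in advance. The same holds for the detected shares below and, with a library left out, for the matching pairs. On the TPM scale the 100 highest genes held 20.7% of the total, against 17.7% of counts. The coefficient of variation was between 19.4% and 30.5% with a library left out, the lowest without replicate 4, and the cause was not tested. Genes with excess variation stayed at 0 in all edgeR alternatives. The 33 DESeq2 dispersion outliers were marked by a different rule without adjusted p-values, so the numbers are not alike. With at least 1 CPM in 2 libraries, 10 counts in every library or 1 count in every library, the detected share was 68.4%, 68.6% and 76.0% in the read-bearing part, and 3.10%, 3.42% and 5.80% on the low-read linkage groups. With a library left out, these shares were 65.4% to 66.6% and 2.75% to 2.83%. The genes apart in replicate 4 numbered 218 at a floor of 10 CPM, where 7363 genes were tested instead of 9811. Gene pairs with matching counts numbered 9 within 5% and 29 within 20%, against 19 within 10%, and between 19 and 22 with a library left out. Partners on low-read parts with under 10% of the count numbered 16 of 16 pairs when at least 1000 counts were asked for, where fewer pairs qualified, 29 of 29 at 20 counts, and 25 of 25 otherwise. Alternatives for gene list levels, list comparisons and leading members were not run, since 0 lists could be filled. No paired analysis was possible because there is only 1 group. Depth limits the detection of single genes to about 0.13 CPM, and does not limit the contrast between parts of the annotation.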

Other observations

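The test in this part was chosen after the correlation had been seen. Neighbouring detected genes in the read-bearing part had slightly similar levels. Undetected genes were left out before pairing, so such genes can lie between neighbours. Pearson's correlation of log2 mean RPKM over 8525 adjacent pairs of detected genes was 0.085, against at most 0.045 in 2000 shuffles within sequences (one-sided permutation p = 0.0005, the smallest these can give). Leaving out neighbours with equal exon number gave 0.066 over 7588 pairs, against at most 0.0475 in the same shuffles. The deviation of replicate 4 from the other libraries, the only library examined in this way, was also correlated between neighbours. The correlation was 0.121 against at most 0.0492 in shuffles, and 0.0836 against at most 0.0443 without equal exon numbers. A local level shared by neighbouring genes is a hypothesis these values are consistent with, at a correlation of 0.085 that leaves most of the variation unexplained. Reads shared between tandem copies may add to it, and tandem copies were not counted.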
